A study of Mus musculus with 6 samples.

How the data were processed

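Total RNA of 3 wild type and 3 irisin knockout samples was extracted with TRIzol, labelled with biotin using the WT Plus kit and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are on a log2 scale and are RMA summaries, 1 per probe set and array, made with affy 1.61.0 in R 3.6.0, per the submitters' processing notes. RMA usually joins background correction, quantile normalization and a robust summary over probes; which of these steps were run, the definition of the probe sets and the genome build are not given in the sources used here. The array medians differ by up to 0.143, so the deposited columns do not share 1 distribution. Values run from 0.093 to 12.96, and no detection calls were used here, so a low value is not told apart from background. The log2 scale itself was inferred from that range and from RMA's usual output.

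The table holds 25206 rows. The platform annotation paired 23185 of them with 1 gene symbol each, 0 with several and 2021 with none; the unnamed rows stayed out of the tests. All 23185 symbols equalled a current symbol in a RefSeq gene table of the mouse assembly GRCm38.p6, which served only for names, neighbours of Fndc5, gene types and lengths of short RNAs. No gene had more than 1 row, so averaging the rows of a gene was not run. Some genes of the lists had no row under their name and were not analysed here.

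Groups were taken from the sample titles. The test of each gene was limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3) with genotype as the only term, two-sided, with Benjamini-Hochberg adjustment over all 23185 genes and a threshold of 0.05. No filter on dim genes was applied. Differences are knockout minus wild type on the log2 scale. Fndc5 was also given an exact permutation test. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 40 lists, beside camera with an estimated correlation, camera on ranks, and fry. Direction of a list is given by its median, and a list is counted as turned in a setting if its median or the direction of camera changed there. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

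The lists, tests, alternatives and naming rule were fixed before the data were examined. Named are Fndc5, up to 10 genes in each direction with the largest difference among those past the threshold, and in each list the members past the threshold, at most 4 by p, or the 2 with the lowest p where none passed. For the genes named by size, the 3 knockout values had to lie on 1 side of the 3 wild type values and the higher group mean above the median of all genes. Predicted genes, microRNAs and small nucleolar RNAs were counted but not named by size.

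On simulated data in the comparison of knockout with wild type (23185 genes), the same code recovered 2 of 67 genes changed by 0.5 log2 units, 33 of 67 changed by 1 and 60 of 66 changed by 2. It called 6 unchanged genes, called the shifted list, and called 0 of 38 lists without shifted genes. The simulated genes were drawn independently, whereas the estimated correlation in the data was 0.59 for the matrix list and 0.83 for fibroblast markers. The list counts therefore do not bear on false calls of lists whose genes move together. Far fewer genes were changed than were called in the data, which makes the adjusted threshold stricter. In that setting small differences were often missed at 3 arrays per group.

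Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 30% or 50% of genes, testing all rows, eBayes with a trend or robust, array weights, the replicate number as a block, leaving out each array, other thresholds and other list tests. Leaving out both arrays numbered 1, and leaving out short non-coding RNA genes, were added after the data were seen. Sex as a covariate was not run, since all 6 arrays had the male pattern.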

Results

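Gene expression was measured in the hearts of FVB mice, an inbred albino strain, with 1 Affymetrix array for each of 6 samples. Of these, 3 samples came from wild type animals and 3 from animals with a knockout of irisin, a peptide hormone cleaved from the membrane protein that Fndc5 encodes. The knockout line was made with Cas9 and 5 guide RNAs, and the animals had eaten chow with 10% fat for 24 weeks, with littermates as controls. Some label fields name the material as cardiomyocytes and another as myocardium, so whether isolated cells or pieces of heart muscle were used is not settled here. Each array is described as coming from an animal, but the labels do not say outright that the 3 arrays of a group are 3 different animals. If they are not, the p-values measure only the spread between these samples, which may be technical. Array medians lay between 2.13 and 2.28 on the log2 scale, and precision is limited by the 3 arrays per group. The question behind the comparison, from the series title, is how loss of irisin alters the heart in relation to insulin resistance and ischaemic injury.

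The targeted gene was lower in the knockout, but not to the same degree in its 3 arrays. Fndc5 (Entrez gene 384061) stood at 8.42, 8.40 and 7.83 log2 units in wild type replicates 1, 2 and 3, a mean of 8.22 ± 0.34 (SD, n = 3). In the knockout arrays it stood at 7.68 in replicate 1, 5.49 in replicate 2 and 5.45 in replicate 3, a mean of 6.21 ± 1.28 (SD, n = 3). Replicate 1 lay 1.45-fold below the wild type mean, whereas the other 2 knockout arrays lay 6.72-fold below it. All 3 knockout values were below all 3 wild type values, and the difference of -2.01 (SE 0.54, 95% interval -3.24 to -0.78) had an adjusted p of 0.0359 in limma. The two-sided exact permutation test of Fndc5 alone gave p = 0.1, the smallest value that 3 arrays against 3 allow. The call was lost with a robust variance model (adjusted p = 0.0635) and without any 1 array other than knockout replicate 1. The adjusted p without wild type replicate 1, 2 or 3 was 0.0736, 0.0806 and 0.0617, and 0.133 and 0.124 without knockout replicate 2 or 3. Without knockout replicate 1 the difference was -2.75, with an adjusted p of 0.00217. The sources used here do not say which part of Fndc5 was deleted, so a remaining signal from probes outside that part is not excluded.

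Beyond Fndc5, knockout and wild type arrays differed across a broad part of the transcriptome. Of 23185 genes tested, 2416 were higher and 1432 lower in the knockout at the adjusted threshold, 16.6% of all genes. Differences of at least 2-fold were seen for 793 of the higher and 389 of the lower genes. Genes whose 3 knockout values did not overlap the 3 wild type values numbered 7916, or 34.1% against the 10% that chance gives. The first principal component held 61.0% of the variance, with the knockout arrays at 31.4 to 40.5 and the wild type arrays at -46.1 to -29.7. The second held 15.0% and set wild type replicate 1 (31.7) apart from wild type replicate 2 (-31.6). Correlations across genes, which are not independent replicates, ran from 0.991 to 0.993 between knockout arrays, 0.980 to 0.982 between wild type arrays and 0.959 to 0.972 between the groups.

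The balance of higher and lower calls depended on how the arrays were scaled. On the deposited values 62.8% of called genes were higher, against 76.4% (3162 higher, 977 lower) after centring each array on its median and 55.2% (1886 higher, 1528 lower) after quantile normalization. Centring moved the median difference of all genes from -0.05 to 0.07, a shift of 0.11. The difference also depended on level, which centring does not change. Genes were ranked by mean level into 10 equal parts. The median difference went from -0.05 in part 1, the dimmest, down to -0.12 in part 5. It rose from there to 0.27 in part 10, the brightest, where 801 genes were higher and 258 lower. The SD of all values was 2.12 to 2.15 on the knockout arrays and 2.00 to 2.06 on the wild type arrays. Counts were smaller without single knockout arrays: 1534 higher and 740 lower without replicate 1, 1403 and 701 without replicate 2, and 1759 and 826 without replicate 3. The labels name no day or batch of extraction or hybridisation, so a batch that ran along with genotype cannot be told apart from it.

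The gene with the largest rise was Acot2, a mitochondrial acyl-CoA thioesterase, at 10.81 ± 0.34 in the knockout and 6.84 ± 0.18 in wild type (SD, n = 3), a 15.7-fold difference (limma, adjusted p = 0.000132). Several others in this group also act in mitochondria. Coq5, a methyltransferase of coenzyme Q synthesis, rose 8.06-fold to 10.18 ± 0.24. Nsun3, which methylates a mitochondrial transfer RNA, rose 9.10-fold, and Gatc, a subunit of the mitochondrial glutamyl-tRNA amidotransferase, rose 8.18-fold. The muscle genes Asb15, Myot and Klhl38 rose 9.43-fold, 7.19-fold and 6.47-fold. Myot encodes the Z-disc protein myotilin and read 7.24 ± 0.02 in the knockout against 4.39 ± 0.46 in wild type. Dhdh, a dihydrodiol dehydrogenase, rose 9.18-fold, Reep6, a shaper of endoplasmic reticulum membranes, 8.44-fold, and the orphan receptor Gpr22 6.67-fold. For these 10 genes the adjusted p lay at or below 0.000675, with standard errors of 0.15 to 0.30 on the log2 scale.

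The genes with the largest falls included smooth muscle and matrix genes. Eln, which encodes elastin, fell by 3.43 on the log2 scale (SE 0.56, limma adjusted p = 0.00474), or 10.8-fold. Col3a1, the type III collagen chain, was 7.22-fold lower at 5.32 ± 0.29 against 8.17 ± 0.56 (SD, n = 3). The smooth muscle genes Cnn1, Tagln and Myl9 were 8.25-fold, 7.12-fold and 6.66-fold lower. The inducible heat shock gene Hspa1a was 9.23-fold lower, the nuclear receptor Nr4a3 7.13-fold lower and the antiproliferative gene Btg3 7.12-fold lower. A pair of short nuclear RNAs completed the group: Rpph1, the RNA part of RNase P, was 8.14-fold lower and Rnu11, a small nuclear RNA of the minor spliceosome, 5.82-fold lower. Wild type arrays were uneven for some of these genes. Cnn1 read 6.03, 3.25 and 7.24 in wild type replicates 1, 2 and 3 and lost its call without any 1 of 5 arrays (adjusted p up to 0.119). Hspa1a lost its call without wild type replicate 3 (0.0548) or knockout replicate 2 (0.0690) or 3 (0.0607), and Tagln without knockout replicate 2 (0.0508).

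**Figure D1:**
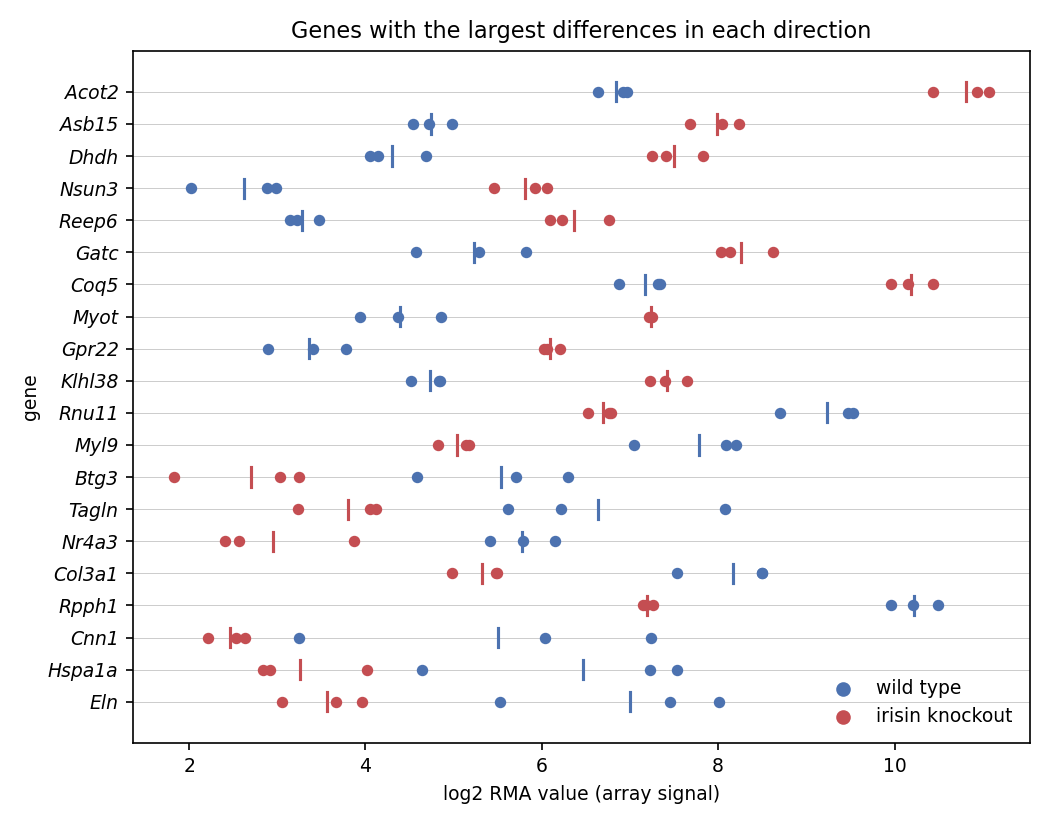
Log2 RMA values on each of the 6 arrays (points) and group means (vertical bars) for the 10 genes with the largest rise and the 10 with the largest fall under the naming rule. The 3 knockout points of every gene lie on 1 side of the 3 wild type points, as for Acot2 at 10.43 to 11.07 against 6.63 to 6.96.

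Of 40 gene lists tested, 17 passed camera with its preset correlation of 0.01, 11 higher and 6 lower in the knockout. Camera compares a list with all other genes, so a list of bright genes could pass as higher through level alone. The brightest of the 10 parts of genes had a median of 0.27. Below it lay the medians of the antioxidant, insulin signalling, oxidative phosphorylation, hypoxia and deacetylase lists, and above it those of the other higher lists. A comparison with genes of like level was not run for each list. With a correlation estimated from the data, 0 of the 40 passed (smallest adjusted p = 0.442), and 0 did so at an unadjusted p under 0.05. The value 0.442 recurs because the adjustment gave it to every list with an unadjusted camera p from 0.0683 to 0.144. That form has few degrees of freedom with 3 arrays per group, so a miss does not show a list to be unchanged. Camera on ranks called 15. After quantile normalization 9 lists passed, namely the 6 lower ones and those of fatty acid use, PPAR targets and the tricarboxylic acid cycle, and the same 9 passed without the dimmest 50% of genes. Fry, which asks whether a list moves 1 way on balance without comparing it with other genes, called 15, and its mixed form 36. These were not all the lists of camera. Fry missed fibroblast markers (adjusted p = 0.0815), immediate early genes (0.143), calcium handling (0.0611), oxidative phosphorylation (0.298) and atrial markers (0.406). It called inflammatory mediators (0.0129), skeletal muscle (0.00753) and macrophage markers (0.0229) as lower, which camera did not.

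Genes of fatty acid use were higher in the knockout. Of 25 genes of fatty acid uptake and oxidation, 15 rose, 0 fell and 10 did not pass (20 higher and 1 lower when adjusted over the list alone), with a median difference of 0.62. Acat1, a mitochondrial thiolase, rose 2.82-fold (SE 0.13 on the log2 scale), the trifunctional protein subunit Hadha 1.91-fold (SE 0.13), the carnitine carrier Slc25a20 2.27-fold (SE 0.16) and the enoyl-CoA isomerase Eci2 2.50-fold (SE 0.19). The list passed camera (adjusted p = 9.57e-10), with adjusted p = 0.442 with an estimated correlation. Targets of the PPAR nuclear receptors rose for 6 of 16 (8 of 16 adjusted over the list alone; median 0.63), led by Acot2, Ehhadh at 0.89, the lipoprotein receptor Vldlr at 0.80 and the lipid droplet protein Plin2 at 0.89. Its adjusted p was 6.81e-05, and 0.442 with an estimated correlation. Expression of the tricarboxylic acid cycle followed: 12 of 21 genes rose and 0 fell (14 higher adjusted over the list alone), with a median of 0.60. Suclg2 rose 3.30-fold, Idh3b 2.60-fold, citrate synthase (Cs) 1.84-fold and Ogdh 1.62-fold. For this list camera gave an adjusted p of 4.34e-09, and 0.442 with an estimated correlation. Without both arrays numbered 1, a setting chosen after the data were seen, 9 genes of fatty acid use, 5 PPAR targets and 8 cycle genes rose.

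Other mitochondrial genes went both ways. Of 24 genes of mitochondrial biogenesis and dynamics, 12 rose and Nrf1 fell (14 higher and 2 lower adjusted over the list alone). Esrrg, an oestrogen-related receptor, rose 2.17-fold, the mitophagy kinase Pink1 2.33-fold, and the ribosomal RNA methyltransferase Tfb1m 1.81-fold, while the fission protein Dnm1l rose by 0.69 on the log2 scale. The median was 0.52 and the adjusted p 0.000514, and 0.442 with an estimated correlation. Nrf1 lost its call in all 6 fits that leave out 1 array each (adjusted p up to 0.155). Oxidative phosphorylation was mixed: 13 of 52 genes rose and 6 fell (14 and 7 adjusted over the list alone). Atp5pb, Ndufc1, Ndufs8 and Ndufb9, subunits of ATP synthase and complex I, rose by 1.16, 1.30, 1.08 and 0.77. Its median of 0.19 (adjusted p = 0.0297, and 0.725 with an estimated correlation) turned to -0.03 after quantile normalization (adjusted p = 0.694). The biogenesis list kept a positive median of 0.28 under that scaling but not its call (0.0827). Leaving out wild type replicate 1 (0.105) or 3 (0.18), or centring each array on its median (0.0614), also ended the call for oxidative phosphorylation. Without both arrays numbered 1, 6 biogenesis genes rose, 6 genes of oxidative phosphorylation rose and 5 fell (adjusted p for the latter list 0.117). Biogenesis genes that rose numbered 7 without wild type replicate 3 or knockout replicate 1 or 2. Genes of oxidative phosphorylation that rose numbered 7 without knockout replicate 1 or 2, and those that fell 3 without knockout replicate 2 or 3.

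Calcium handling and ion channel genes rose for 9 of 27, while Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell (13 and 1 adjusted over the list alone). Kcnip2, a subunit of the transient outward potassium channel, rose 4.23-fold to 8.92 ± 0.03 (SD, n = 3). Trdn, which encodes triadin, rose 2.08-fold, and the potassium channels Kcnq1 and Kcnj11 rose 1.52-fold and 1.46-fold. The median was 0.52 and the adjusted p 0.00073, and 0.466 with an estimated correlation. Without both arrays numbered 1, 4 of these genes rose and 1 fell. Leaving out any 1 knockout array also left 4 genes higher, and leaving out wild type replicate 3 took the median to 0.26. Hrc lost its call in 5 of the 6 fits that leave out 1 array (adjusted p up to 0.125) and Kcnj11 in 2. Among sarcomere genes Myot, Lmod2, Actn2 and Cap2 rose, 0 fell and 17 of 21 did not pass (4 higher adjusted over the list alone; adjusted p = 0.133). Their median of 0.16 turned to -0.09 after quantile normalization, and without wild type replicate 2 the list passed as higher (0.24, adjusted p = 0.0347). Cap2 lost its call in 4 of the 6 fits without 1 array (up to 0.125), and 3 sarcomere genes fell without wild type replicate 1.

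Genes of antioxidant defence rose for 7 of 28 and fell for 0 (8 higher adjusted over the list alone). Catalase (Cat) rose 6.29-fold to 10.80 ± 0.30, Nqo1 2.80-fold, Prdx3 2.41-fold and Gsr 1.73-fold (adjusted p for the list 0.00203, and 0.442 with an estimated correlation). In the autophagy list 8 of 22 rose, and Ctsl and Map1lc3a fell (12 and 3 adjusted over the list alone). Ulk1, the initiating kinase, rose 1.97-fold, Atg12 3.03-fold, Map1lc3b 1.85-fold and the protease Ctsb 1.68-fold. That list had an adjusted p of 0.00173, and 0.442 with an estimated correlation. The insulin signalling list held 10 genes that rose and 3 that fell among 32 (12 and 4 adjusted over the list alone), with a median of 0.21. Grb14, an adaptor that inhibits the insulin receptor, rose 2.43-fold, the AMP-activated kinase subunit Prkaa2 2.91-fold, Tsc2 1.83-fold and Gsk3a 1.73-fold, whereas Igf1r, Akt1 and Ptpn1 fell. Its adjusted p was 0.0145, and 0.442 with an estimated correlation. After quantile normalization the calls for calcium handling (0.143), antioxidant defence (0.116), autophagy (0.288) and insulin signalling (0.481) were lost. The insulin signalling genes called higher numbered 5 without wild type replicate 3 or knockout replicate 1 or 3 and 4 without knockout replicate 2, and autophagy genes 5 without knockout replicate 2 or 3. Autophagy genes that fell numbered 0 without knockout replicate 1 or 2, 1 without replicate 3 and 0 without both arrays numbered 1. Igf1r, Akt1 and Ptpn1 lost their calls in 2, 4 and 3 of the 6 fits without 1 array.

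A pair of further lists passed narrowly. In the hypoxia and angiogenesis list 7 of 24 rose and Vegfa fell (9 and 2 adjusted over the list alone). Vegfb rose 2.65-fold, the prolyl hydroxylases Egln3 and Egln1 4.67-fold and 1.72-fold, and the kinase Pdk1 1.98-fold (adjusted p for the list 0.0473, and 0.466 with an estimated correlation). Its median of 0.11 turned to -0.07 after quantile normalization. Among histone deacetylases and sirtuins Hdac9, Sirt2 and Hdac11 rose by 1.09, 0.90 and 0.71 and Hdac7 fell by 0.92, with 14 of 18 not passing (4 higher and 1 lower adjusted over the list alone). The list had an adjusted p of 0.0473, and 0.442 with an estimated correlation. Neither list passed after either scaling (0.0620 to 0.651), nor without wild type replicate 1 or 3 or knockout replicate 3 (0.0542 to 0.137). Without knockout replicate 2 the deacetylase list also missed (0.0518). Over the 6 fits without 1 array Vegfa lost its call in 5 (adjusted p up to 0.101) and Hdac11 in 3.

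**Figure D2:**
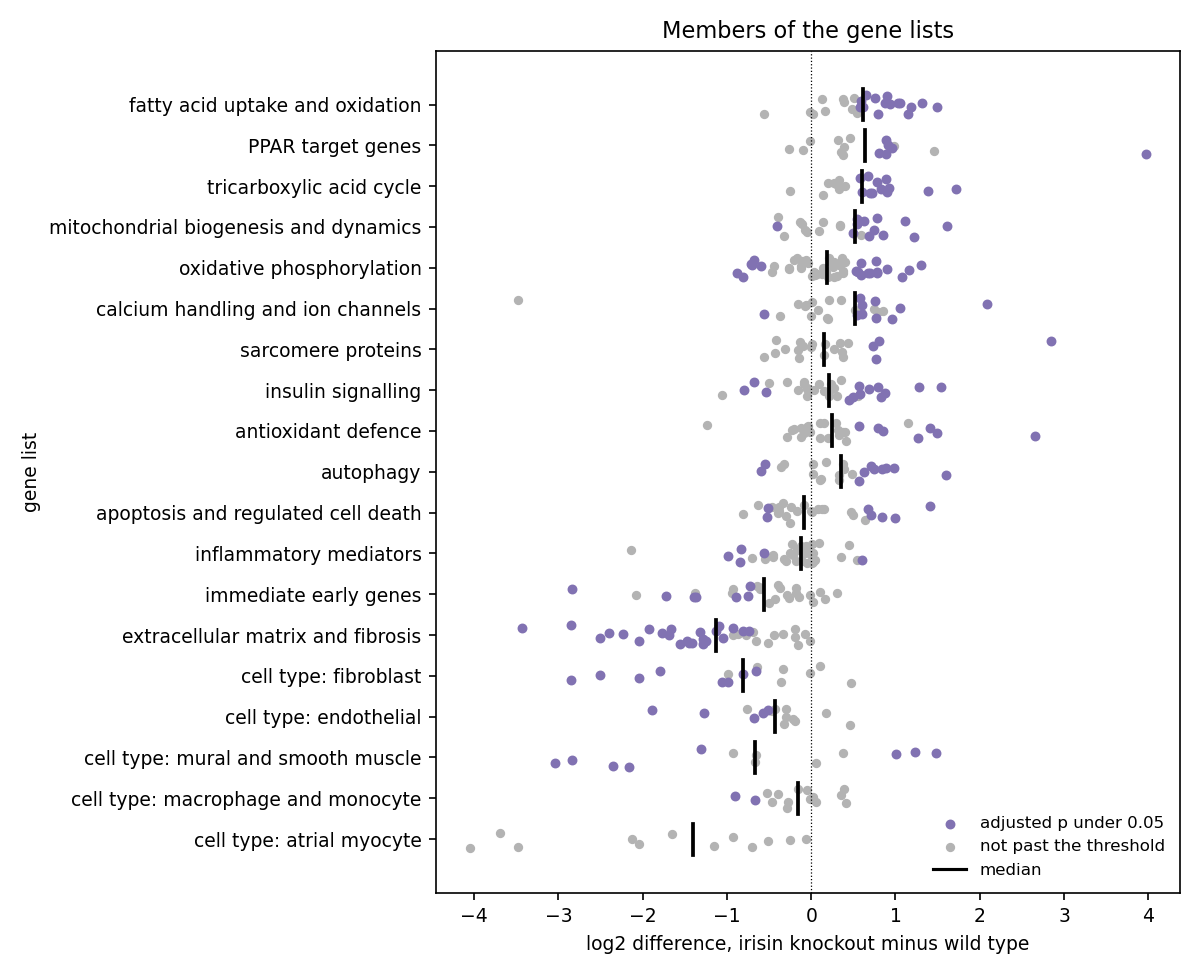
Log2 difference, knockout minus wild type, of each tested member of 19 gene lists, with purple points for genes past the adjusted threshold, grey points for the rest and a black bar at the list median. The median lies at 0.62 for fatty acid uptake and oxidation and at -1.13 for the extracellular matrix; after quantile normalization those of oxidative phosphorylation, with -0.03, and of sarcomere proteins, with -0.09, lie below 0.

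Extracellular matrix genes were lower in the knockout as a group. Of 37 genes of matrix and fibrosis, 24 fell, 0 rose and 13 did not pass (29 lower adjusted over the list alone), with a median of -1.13. Thbs1, which encodes thrombospondin-1, was 5.27-fold lower, Col3a1 7.22-fold lower, and the basement membrane collagens Col4a1 and Col4a2 were 3.79-fold and 3.16-fold lower. The list had a camera adjusted p of 1.9e-13, and 0.442 with an estimated correlation. Fibroblast markers, which share collagens with that list, fell for 8 of 15 (10 adjusted over the list alone; median -0.81). Col1a1 was 5.66-fold lower, Col1a2 4.13-fold lower and Gsn, an actin-severing protein, 1.75-fold lower (adjusted p for the list 6.81e-05, and 0.580 with an estimated correlation). Wild type arrays differed here too: the mean over the matrix list was 6.48, 5.64 and 6.53 in replicates 1, 2 and 3, against 4.94 to 5.07 in the knockout. Without both arrays numbered 1, 13 matrix genes and 5 fibroblast markers fell. Matrix genes that fell numbered 15, 14 and 13 without knockout replicate 1, 2 or 3, and fibroblast markers 4 and 5 without replicate 2 or 3.

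Other cell type markers did not all move with the matrix. Endothelial markers fell for 5 of 15 (8 lower and 1 higher adjusted over the list alone): Vwf by 1.89, Egfl7 by 1.27, Eng by 0.57, Pecam1 by 0.52 and Fabp4 by 0.68. The median was -0.43 and the adjusted p 0.00196, and 0.442 with an estimated correlation. Of 15 macrophage and monocyte markers, Mrc1 and Cd14 fell and 13 did not pass (the same number adjusted over the list alone; adjusted p = 0.367). Mural and smooth muscle markers split, with 3 of 13 higher and 5 lower (4 and 7 adjusted over the list alone; adjusted p = 0.367). Of this list Rgs5, Kcnj8 and Abcc9 rose by 1.23, 1.49 and 1.01. The smooth muscle genes Acta2, Tagln, Myh11 and Cnn1 fell by 2.16, 2.83, 2.35 and 3.04, and Mustn1 fell by 1.30. Lymphocyte markers passed only for Cd4, which rose by 0.77, and adipocyte markers only for Thrsp, which rose by 0.91 (the same counts adjusted over each list alone; adjusted p = 0.161 and 0.391). Of 12 mesothelial markers Msln and Wt1 fell (the same adjusted over the list alone; adjusted p = 0.167). Both calls were lost in 5 of the 6 fits without 1 array (up to 0.114 and 0.127), and 0 mesothelial markers were called lower without wild type replicate 3, without any 1 knockout array or after centring. Without wild type replicate 2 the adipocyte list passed as lower (median -0.30 in place of -0.14, adjusted p = 0.0224, 5 genes called lower), as did the mesothelial list (0.0359); without wild type replicate 1 the adipocyte median was -0.02. Without knockout replicate 1, 2 or 3, respectively, 2, 1 and 2 mural and smooth muscle markers were called lower, and 3 and 2 endothelial markers without knockout replicate 1 or 2. Over all 6 fits without 1 array Fabp4 lost its call 5 times (adjusted p up to 0.157), Cd14 and Abcc9 4 times, Myh11 and Mustn1 3 times and Eng and Pecam1 in 2 fits each.

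Atrial myocyte markers varied from array to array within both groups. None of 12 passed singly in limma, nor adjusted over the list alone, and 3 had an unadjusted p under 0.05. With the replicate number as a block, which the labels do not explain, 4 were called lower. Myl4, the atrial light chain, differed by -4.05 (SE 1.35, adjusted p = 0.0792) and Dkk3 by -2.04 (SE 0.70, 0.0872). As a list they were lower (median -1.41, adjusted p = 0.0415, and 0.725 with an estimated correlation). The size of that difference leaned on wild type replicate 1. Without wild type replicate 1 alone the median was -0.16, 2 genes were called higher and the list did not pass (0.830). Without both arrays numbered 1 the median was -0.32, 4 genes were called lower and the list passed (0.0467). Without knockout replicate 1 the median was -1.62, 1 gene was called lower and the list passed (0.00829). It did not pass without knockout replicate 2 (0.0758) or 3 (0.124). Sln and Myl7, 2 genes chosen after their values were seen, show the spread. Sln read 10.80, 3.83 and 5.54 in wild type replicates 1, 2 and 3 and 6.98, 1.39 and 1.36 in the knockout. Myl7 read 10.16, 4.22 and 5.55 in wild type and 5.09, 2.44 and 1.33 in the knockout.

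**Figure D3:**
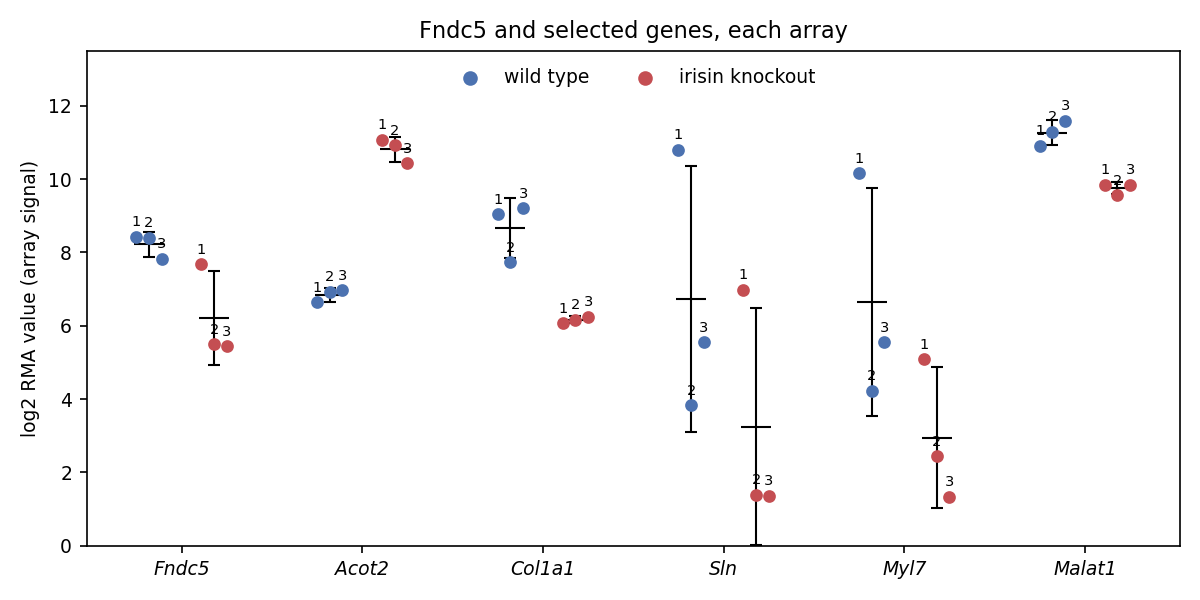
Log2 RMA values of 6 genes on each array, numbered by replicate, with black bars for the group mean and SD (n = 3). Fndc5 in knockout replicate 1 (7.68) lies near the wild type arrays, while Acot2, Col1a1 and Malat1 in that array lie with the other knockout arrays, and Sln and Myl7 are highest in replicate 1 of each group.

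Markers of 4 further kinds of cell, and sex-linked genes, gave no gene past the threshold in limma, over all genes or adjusted over the list alone. They were 8 erythroid genes (median -0.60, adjusted p = 0.432), 18 skeletal muscle genes (-0.15, 0.0886), 10 genes of Schwann cells and nerve (-0.16, 0.367), 10 neutrophil genes (-0.07, 0.601) and 8 sex-linked genes (-0.04, 0.970). At an unadjusted p under 0.05 the counts were 3, 5, 3, 0 and 2. Hbb-bs and Hbb-b1 differed by -1.01 and -2.19, and Hbb-b1 read 7.35 in wild type replicate 2 against 2.67 to 4.49 on the other arrays. Atp2a1 and Tnnc2 differed by -0.40 and -0.48, Nefm and Sox10 by 0.38 and -0.39, S100a9 and Ly6g by -0.26 and -0.19, and Kdm6a and Kdm5c by 0.43 and -0.37. All 6 arrays had the male pattern, with Xist at 1.05 to 1.32 and the Y-linked gene Eif2s3y at 5.80 to 6.34.

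Immediate early genes, the first to respond to a stimulus, were lower. Of 28, 7 fell and 0 rose (9 adjusted over the list alone), with a median of -0.56. Nr4a3 was 7.13-fold lower, Atf3 3.29-fold, Egr3 2.58-fold and Maff 1.66-fold (adjusted p for the list 0.000143, and 0.580 with an estimated correlation). The mean over the list was 5.16 in wild type replicate 1, 4.14 in replicate 2 and 4.71 in replicate 3, against 3.97 to 4.01 in the knockout, and 3 genes fell without both arrays numbered 1. Without wild type replicate 2, 15 fell, and without knockout replicate 1, 2 or 3 it was 3, 2 and 2. Egr3 and Maff each lost their call in 3 of the 6 fits without 1 array. Heat shock genes split: the small heat shock proteins Hspb7, Hspb6 and Hspb8 rose 4.02-fold, 3.41-fold and 1.72-fold and the co-chaperone Bag3 2.02-fold, whereas Hspa1a, Hspa1b and Dnaja1 fell (of 20; the same counts adjusted over the list alone). That list did not pass (adjusted p = 0.125), although without wild type replicate 1 it did (0.0116), and its median turned from 0.20 to -0.05 after quantile normalization. Hspa1b lost its call in 5 fits without 1 array (up to 0.118).

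The list of irisin, its reported receptor and related genes was lower (median -0.28, adjusted p = 0.0321, and 0.442 with an estimated correlation). Fndc5 itself and Fndc3b, a relative of it, fell and 8 of 10 did not pass (5 lower adjusted over the list alone). Since Fndc5 is the targeted gene, part of the fall of this list was fixed by the design. The list was not tested without Fndc5. The call was lost without wild type replicate 1 (0.144) or knockout replicate 3 (0.0582), and without both arrays numbered 1 (0.15). Among the 19 nearest coding genes of Fndc5 with values, Bsdc1 and Sync rose by 0.98 and 1.36 and Trim62 and Rbbp4 fell by 0.75 and 0.55 (3 and 2 adjusted over the list alone; adjusted p = 0.970). Rbbp4 lost its call in 4 of the 6 fits without 1 array (up to 0.139) and Trim62 in 2. For these neighbours the median (-0.11) and the mean (0.02) differed in sign.

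Glucose uptake and glycolysis did not pass as a list (adjusted p = 0.125), with a median of 0.10 that turned to -0.08 after quantile normalization. In it 5 of 21 genes rose and Pfkfb2 fell (5 and 1 adjusted over the list alone). The muscle enolase Eno3 rose 1.78-fold, the glycogen phosphorylase Pygm 1.59-fold, the glucose transporters Slc2a4 and Slc2a1 1.67-fold and 2.02-fold, and the glycogen synthase Gys1 by 0.65. Without wild type replicate 2 the list passed as higher (0.0307), and 3 genes rose without knockout replicate 2. Pfkfb2 lost its call in 3 of the 6 fits without 1 array, Gys1 in 2 and Slc2a1 in 1. Cardiac stress genes also went both ways (adjusted p = 0.435): the slow myosin Myh7 rose 3.31-fold and Xirp2 1.53-fold, while Cd44 and Ccn2 fell by 0.86 and 1.77, and 15 of 19 did not pass (2 and 2 adjusted over the list alone). Without wild type replicate 2, 6 stress genes were called lower, and without wild type replicate 1 it was 4 higher and 1 lower. Ccn2 ran from -2.41 to -1.19 over the fits without 1 array and lost its call in 5 of 6 (adjusted p up to 0.125), and Xirp2 in 4. In the circadian list 4 of 18 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.351). The output gene Dbp rose 2.74-fold, Nr1d1 1.85-fold, Bhlhe41 by 0.97 and Usp2 by 0.62, and the repressors Per2, Cry1 and Per3 fell by 0.94, 0.84 and 0.72. Per3 lost its call in 5 of the 6 fits without 1 array (up to 0.105), Usp2 in 3 and Bhlhe41 in 1.

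Inflammatory mediators did not pass as a list (median -0.12, adjusted p = 0.0702): Ccl9, Il1r1, Ccl7 and Cxcl2 fell by 0.98, 0.83, 0.84 and 0.56, and Ccl11 rose by 0.60, out of 34 (1 higher and 6 lower adjusted over the list alone). Without wild type replicate 2 that list passed as lower (-0.16, adjusted p = 0.0359), but Ccl7, Ccl11 and Cxcl2 each lost their call in 5 of the 6 fits without 1 array (adjusted p up to 0.0970, 0.127 and 0.164). In the interferon list Gbp7 and Ifit2 rose by 1.17 and 0.83 and Irf9, Ifi27l2a, Oas2 and Stat2 fell by 0.74, 0.81, 1.00 and 0.56, out of 28 (2 and 4 adjusted over the list alone; adjusted p = 0.184). Over the same 6 fits Stat2 lost its call 5 times (up to 0.109), Oas2 in 2 and Ifi27l2a in 1. Of 18 genes of antigen presentation H2-D1 and H2-K1 fell by 1.16 and 0.66 (2 higher and 3 lower adjusted over the list alone; adjusted p = 0.970), and the list median (0.05) and mean (-0.02) differed in sign. H2-K1 lost its call in 4 of the 6 (up to 0.101). In the apoptosis list Mdm2, Casp8, Bcl2l11, Bcl2 and Bnip3l rose by 1.41, 1.00, 0.67, 0.72 and 0.84, and Apaf1 and Fas fell by 0.51 and 0.52, out of 27 (8 and 5 adjusted over the list alone; adjusted p = 0.970). Its median (-0.08) and mean (0.04) differed in sign as well, and the genes that rose numbered 3, 2 and 3 without wild type replicate 3 or knockout replicate 1 or 3. Apoptosis genes that fell numbered 0 without any 1 knockout array, 0 with the eBayes trend, 0 after centring (8 rose) and 4 without wild type replicate 1.

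In the list of endoplasmic reticulum stress Atf3 and Atf4 fell by 1.72 and 0.73, and Sel1l, Atf6 and Dnajb9 rose by 0.82, 0.66 and 1.14, out of 25 (3 and 3 adjusted over the list alone; adjusted p = 0.970). Dnajb9 lost its call in 3 of the 6 fits without 1 array and Atf6 in 1, and 4 genes of the list fell without wild type replicate 3. Cell cycle genes passed for 3 of 25: Tyms and Plk1 fell by 0.90 and 0.44 and Aurkb rose by 0.52 (the same adjusted over the list alone; adjusted p = 0.499). Of these only Tyms kept its call in every fit without 1 array; Plk1 and Aurkb lost theirs in 5 of 6 (up to 0.120 and 0.0941). Of 28 cytosolic ribosomal protein genes Rplp1 and Rpl10 fell by 0.96 and 0.51 and Rps16 rose by 1.19 (the same adjusted over the list alone; adjusted p = 0.499). Rpl10 lost its call in 5 of the 6 fits (up to 0.126) and Rps16 in 3 (up to 0.0983). Genes that complete a count of 5 or fewer, beyond the 4 with the lowest p in each list, were named after their values were seen.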

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

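The count of unnamed probe sets in this part was chosen only after the data were seen. Among the 2021 probe sets with no gene name, which the comparison above does not use, 88 were higher and 173 lower in the knockout at the adjusted threshold of limma fitted to all 25206 rows. They carry a difference between the groups outside the named genes, although a smaller share of them was called than of the named rows. In that same fit 2403 of the 23185 named rows were higher and 1412 lower. The unnamed calls were thus mostly lower and the named calls mostly higher. What these probe sets measure was not analysed here.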

How the results depend on the processing

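Of the alternatives, leaving out both arrays numbered 1 and leaving out short non-coding RNA genes were chosen after the data were seen. After quantile normalization 3008 of the 3848 genes called on the deposited values kept their call, and 0 changed sign. That scaling moved the median difference of all genes by 0.0426, so a change of sign was unlikely for called genes. Fndc5 stayed lower throughout, at -2.75 to -1.63 without single arrays, but lost its call under robust eBayes (-2.01, adjusted p = 0.0635; 0.00217 to 0.133 over all alternatives) and without any array other than knockout replicate 1. Without single arrays the counts ran from 1403 to 2570 higher and 701 to 1593 lower, lowest without knockout replicate 2 and highest without wild type replicate 1. Lower genes numbered 938 without both arrays numbered 1 and 2212 at an adjusted p under 0.10. The lists called fell from 17 to 9 after quantile normalization and to 0 with an estimated correlation, and ran from 13 to 22 without single arrays. Without the dimmest 50% of genes 9 lists passed, and those lost were all among the higher ones. There fewer genes were tested, and the median difference of all genes was 0.055 in place of -0.045. Whether the replicate numbers pair the samples stays open. Deviations of same-numbered arrays correlated weakly across genes, at 0.0896, 0.0478 and 0.07, but 5 of 6 arrays correlated best with their own number. The labels do not tie a number to a litter, batch or day, so the main tests used no block. With the replicate block there were 2247 higher and 1330 lower genes, 15 lists, and -2.01 for Fndc5 (adjusted p = 0.014). Under it the atrial list had 4 genes called lower (0 without it; adjusted p = 0.000289).

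Lists that turned had not passed on the deposited values, except oxidative phosphorylation and hypoxia, and none passed where it turned; the cause was not tested. After quantile normalization the medians were -0.095 for sarcomere proteins, -0.031 for oxidative phosphorylation, -0.080 for glycolysis, -0.15 for apoptosis, -0.050 for heat shock, -0.029 for circadian, -0.066 for hypoxia, 0.0023 for cell cycle and 0.030 for neutrophil genes. After centring they were 0.029 for apoptosis, 0.020 for interferon, 0.049 for endoplasmic reticulum stress, 0.029 for cell cycle, 0.045 for ribosomal, 0.042 for neutrophil, 0.070 for sex-linked genes and 0.0050 for neighbours of Fndc5. Without the dimmest 30% they were -0.085 for apoptosis and -0.078 for the neighbours; without the dimmest 50%, -0.17 for apoptosis, -0.066 for antigen presentation and 0.034 for ribosomal genes. With all rows they were 0.048 for antigen presentation and -0.041 for sex-linked genes; with array weights, -0.077 for apoptosis; with the replicate block, -0.062 for endoplasmic reticulum stress. Without both arrays numbered 1 they were -0.076 for cardiac stress, -0.040 for apoptosis, 0.072 for antigen presentation and -0.026 for endoplasmic reticulum stress. Where the median kept its sign in these settings, the direction of camera turned. Ranges without single arrays, for lists that turned there, were -0.38 to -0.058 for cardiac stress, -0.0014 to 0.057 for antigen presentation, -0.11 to -0.011 for endoplasmic reticulum stress, -0.14 to 0.016 for apoptosis, -0.95 to 0.032 for erythroid, -0.095 to 0.048 for sex-linked genes and -0.17 to -0.040 for neighbours of Fndc5. With no detection calls, how far dim genes stand above background is unknown; 296 of the 3848 called genes lay below the median level.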

Other observations

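The gene groups in the next 2 paragraphs and all tests below them were chosen only after the result was seen, apart from the counts over splits of the arrays, which were planned. Branched-chain amino acid breakdown genes were higher in the knockout: 15 of 19 rose in limma and 0 fell, with a median of 0.83. The breakdown itself was not measured. Dbt and Bckdhb, subunits of the branched-chain ketoacid dehydrogenase, rose by 1.59 and 1.56, and Aldh6a1 by 1.60. The kinase of that enzyme, Bckdk, rose by 1.25. Bckdha and Bcat2, at 0.25 and 0.33, were among the genes that did not pass. Peroxisome genes rose for 13 of 24, with Acaa1a the 1 gene that fell. Pex11a, which acts in peroxisome division, rose by 1.98. Of 12 coenzyme Q synthesis genes 5 rose, namely Coq5, Coq3, Coq8a, Pdss2 and Coq10a. Coq10a lost its call in 4 of the 6 fits without 1 array, Pdss2 in 2 and Acaa1a in 1. With an estimated correlation the adjusted p was 0.0986, 0.0619 and 0.218. After quantile normalization 12, 10 and 4 genes of the 3 groups rose, and without both arrays numbered 1 it was 9, 9 and 3. In a list of creatine and phosphagen genes Slc6a8, the creatine transporter, and Ak3 rose, and 0 of 12 fell. The median of that list, 0.05, turned to -0.08 after quantile normalization. Ketone body use had 4 genes, of which 3 rose, and 2 rose after quantile normalization or without both arrays numbered 1.

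Among imprinted growth genes Peg3, Meg3, Igf2 and Ndn fell by 1.66, 2.01, 1.07 and 0.51, and Asb4 and Grb10 rose by 1.44 and 0.69, out of 15 (adjusted p = 0.195, and 0.314 with an estimated correlation). Ndn lost its call in 5 of the 6 fits without 1 array (adjusted p up to 0.117) and Grb10 in 1. Short non-coding RNA genes were lower: 92 of 117 fell and 0 rose, with a median of -1.38 that was -1.51 after quantile normalization and -1.27 after centring. Snora75 fell by 5.81 and Snora62 by 3.90. The class had an adjusted p of 9.07e-43, and 0.0619 with an estimated correlation.

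Fndc5 in knockout replicate 1 lay close to wild type. A wild type sample handled like the wild type arrays, but under a knockout label, is argued against. Replicate 1 lay nearer to the other knockout arrays for 96.1% of the 2273 genes other than Fndc5 called without it. Admixed RNA from such a sample is argued against too. This rests on 62 genes that were lower by 2 log2 units in the other knockout arrays. On the linear scale replicate 1 stood a median fraction of 0.0311 of the way to wild type, against 0.637 for Fndc5. Only 2 of the 62, Hamp and Sln, reached the fraction of Fndc5. A batch that ran along with genotype cannot be told apart from it. A wild type animal handled with the knockout samples in such a batch is therefore not excluded. Atrial tissue as the source was judged by 4 genes, Sln, Myl7, Myl4 and Mybphl, and not by other atrial genes. By the lowest of the 4, wild type replicate 1, with more atrial signal, would exceed the other wild type arrays by 2280 linear units of Fndc5. It exceeded them by 60.8, a ratio of 0.0266. A hypothesis that stays open is that this animal carried another Fndc5 allele, as could arise with 5 guide RNAs, which was not tested.

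The fall of short non-coding RNAs may come from how short RNA was recovered, from a smaller share of nuclear RNA, or from genotype. Loss graded by length was not seen, with a Spearman rho of -0.0391 between length and difference over 93 genes (permutation p = 0.709), but loss that does not depend on length cannot be told apart from genotype here. Of 13 long nuclear RNAs 6 fell, among them Malat1 at -1.51 and Neat1 at -1.31, with a median of -0.49 (adjusted p = 0.0986 with an estimated correlation), or -0.995 over the 10 above the median level, where Tug1 alone was not lower (0.0019). A smaller share of nuclear RNA in the knockout samples stays open, since these RNAs did not move alike and the design does not separate it from an effect of genotype.

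Matrix genes were lower and fatty acid genes higher in the knockout, which could reflect tissue makeup. An even fall of all non-myocyte signal was not seen, because matrix scores fell by 1.08 (SE 0.321) more than macrophage scores. Macrophage scores fell too, by 0.202. Both scores used only genes above the median level. Over all genes of each list, macrophage means of 3.86 to 4.08 per array lay below the 4.94 to 6.53 of the matrix list. With no detection calls, background may have shrunk the macrophage difference. Endothelial markers were not dim, with list means of 6.64 to 6.73 in wild type and 6.11 to 6.30 in the knockout. Their mean difference was -0.48, against -1.22 for the matrix list. These values argue against an even loss of all non-myocyte cells as the whole source of the matrix fall. A smaller share of all non-myocyte cells stays open as a part of it, since macrophage and endothelial markers fell too. For the fatty acid genes a smaller share is argued against. There 16 sarcomere genes of the same level range had a median of 0.16 against 0.616 (permutation p over genes, which are not independent, 0.0196). Less vessel, valve or atrial tissue stays open for the matrix genes too. Wild type replicate 2, the wild type array with the least atrial and smooth muscle signal, exceeded the knockout mean by a median of 0.516 over 34 matrix genes, against 1.5 for replicates 1 and 3, and 1 array cannot settle it.

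The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2416 higher and 1432 lower genes, against 0 and 0 as the highest of the other splits, so 1 of 10 splits reached each count. For lists, 3 of 10 splits reached the real 17, with a highest other of 19. The splits that joined wild type replicates 1 and 3 with 1 knockout array gave 19, 18 and 15 lists, which points to a structure that sets these arrays apart from wild type replicate 2.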
